A study of Mus musculus with 15 samples.

How the data were processed

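RNA from retinas of CD-1 mice at postnatal day 2 was sequenced in bulk, in 15 samples that the labels place in 3 groups of 5. WT denotes retinas homozygous for a floxed (conditional) Neurog2 allele without Cre. HET denotes retinas that carry Cre with 1 floxed allele, and MUT those that carry the same Cre with both alleles floxed. Total RNA was purified with a Zymo column kit and libraries were made by a core facility with Illumina protocols, per the labels' protocols; whether RNA with a poly(A) tail was selected, and whether the libraries kept strand, is not given in the sources used here.

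Bowtie2, Cufflinks, Cuffdiff and the mouse genome build mm10 are named in the submitters' processing notes, without versions. The authors deposited 3 Cuffdiff tables at the level of transcripts, 1 for each pair of groups, with an Ensembl transcript and gene identifier, a gene symbol and a locus per row, per the file headers. Each row gives an FPKM value (fragments scaled to transcript length and to the number of mapped fragments) for each of the 2 groups, which the authors computed over the pooled replicates of the group. Each row also holds the authors' log2 fold change (the second group over the first), a test statistic, which is a score without a fixed range, a p-value and a q-value, as deposited. Values per sample were not analysed here, so no standard deviation between samples, no sequencing depth per sample and no recount without 1 sample can be given, and the number of samples per group comes from the labels alone. The labels do not say whether the samples of a group came from separate animals, so that the authors' p-values measure the spread between these samples, which may be technical.

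The tables held 44119, 44526 and 43959 rows for WT against HET, WT against MUT and HET against MUT, from 15871, 15948 and 15798 gene symbols. No row had an FPKM of 0. The deposited log2 fold change differed from the log2 ratio of the 2 deposited FPKM values by at most 5.12e-05. The smallest deposited p-value was 5e-05 in each table and was shared by 21, 51 and 27 rows. The deposited q-values at that p imply at least 29, 58 and 29 such rows among the authors' tests, so further tests entered their correction that were not analysed here. Because p-values stop at 5e-05, the Benjamini-Hochberg procedure over the rows of a table needs 45 rows at that p in each comparison with WT, and 44 in HET against MUT, before any of them reaches a q-value under 0.05. The p-values were large for most rows, with means of 0.69, 0.68 and 0.70.

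Gene symbols that a spreadsheet had turned into dates (98, 99 and 93 rows) were restored through the gene identifier. Gene class and transcript length were taken from GENCODE M release 21, whose coordinates are on the same assembly as mm10; gene identifiers matched for 99.7% of rows in each table and transcript lengths for 98.8%. Loci are given as in the deposited tables, counted from 1, and a locus can span overlapping genes.

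The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. A transcript was called where the authors' q-value was under 0.05. The standard error of a log2 fold change was taken as the absolute ratio of the deposited fold change to the deposited test statistic, and each ± after a log2 fold change is this implied error. Cuffdiff's p-values do not follow from a normal approximation to that ratio, so a row can have the smallest p at a ratio under 2. Of the 25 gene lists, 3 were defined by a pattern of symbols (histone, ribosomal protein and small RNA genes) and the rest by named markers of retinal cell types, other cell types the dissection could hold, and processes. FPKM values of a gene's transcripts were summed, a gene needed 0.5 FPKM or more in either group, and a list was described by the median of log2 ratios of (FPKM + 0.1), beside its percentile among 10000 random lists of the same size, matched on mean FPKM in 20 bins. A median outside the middle 95% of those random lists is called outside the random range. This describes the pooled libraries, since genes are not replicates. Ratios on the scale of log2 (FPKM + 0.1) understate changes of low genes. Beside the count of members called over all rows, the count adjusted over the list alone is given. Rows within 10 Mb of Neurog2, with 1 FPKM or more in either group, were compared with all other rows by Fisher's exact test (two-sided).

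Named genes were, for each comparison, the 10 called rows with the largest log2 increase and the 10 with the largest decrease among those with 1 FPKM or more in either group, called members of the fixed lists as examples, and Neurog2 in all comparisons. Results that need some genes are not reported here. Other genes named were chosen after their values were seen, which is said where they appear. Alternatives included q-value thresholds of 0.01 and 0.10, a recomputed correction, a filter at 1 FPKM, a minimum absolute log2 fold change of 1, a normal approximation to the test statistic, 1 row per symbol, centred fold changes, pseudocounts of 0.01 and 1, and list filters at 0 and 2 FPKM.

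The steps were tested on simulated data. In each comparison 20 of 20 lists of 20 genes shifted by 0.3 were found above the random range, over 14799, 14845 and 14777 genes. Of 40 unshifted lists, 5 lay outside the random range in WT against HET and 1 in each of the other comparisons. The count of called rows recovered 200 of 200 changed rows in each table, with 8, 11 and 20 false rows. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.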

Results

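Bulk RNA-seq was carried out on retinas of CD-1 mice at postnatal day 2, when rods, amacrine cells, bipolar cells and Müller glia are still being born. The 15 samples fell into 3 groups of 5: WT (floxed Neurog2 without Cre), HET (Cre with 1 floxed Neurog2 allele) and MUT (Cre with both alleles floxed). Neurog2 is a proneural basic helix-loop-helix transcription factor. The values were FPKM per transcript pooled over the samples of a group, so they carry no spread between samples, and the depth of each sample is unknown.

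The targeted gene was examined first. Neurog2 (ENSMUSG00000027967.8, chromosome 3, 127633135 to 127635631, mm10) was at 59.5 FPKM in WT and 10.6 FPKM in MUT in the authors' deposited table, a log2 fold change of -2.49 ± 0.32 (q = 0.0388). Against HET, the authors' deposited table listed 59.2 FPKM in WT and 42.4 FPKM in HET, a log2 fold change of -0.48 ± 0.28 (p = 5e-05, q = 0.0769). Between HET and MUT, the value was -2.01 ± 0.25 in the authors' deposited table (p = 5e-05, q = 0.0762). The direction was that of the labels in each table.

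**Figure D1:**
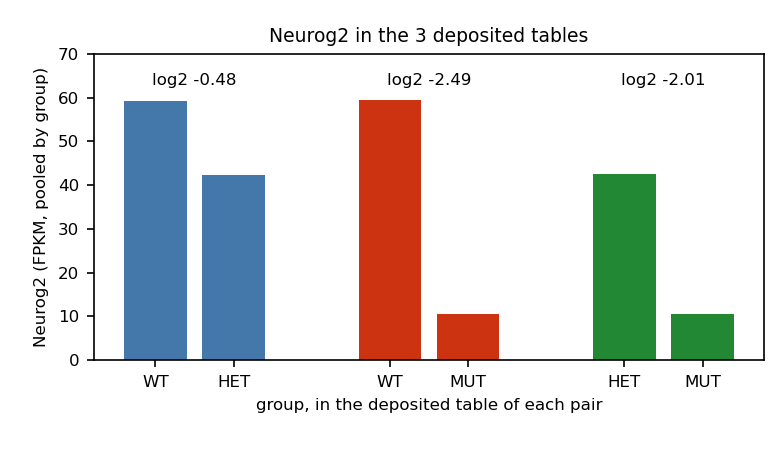
Neurog2 level in FPKM (vertical axis) in the 2 groups of each of the 3 deposited tables (horizontal axis), with the deposited log2 fold change above each pair. Bars are values pooled by the authors over a group and have no error bars; MUT is at 10.6 FPKM against 59.5 FPKM in WT.

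The comparison of WT with MUT asks what changes with loss of both Neurog2 copies together with the presence of Cre. Besides Neurog2, the authors' deposited table called Neurod2, a basic helix-loop-helix factor of amacrine cells, at -0.84 ± 0.42, and Sox11, a transcription factor of newborn neurons, at -0.69 ± 0.31, both lower in MUT. Among transcripts that rose, the authors' deposited table listed Abcd4, a transporter of cobalamin, at 1.75 ± 0.36, Moxd1, a monooxygenase, at 1.26 ± 0.54, Zic1, a zinc finger transcription factor, at 0.79 ± 0.38, and Cldn5, a tight junction protein of endothelial cells, at 0.70 ± 0.38. In all, 51 transcripts of 51 genes were called in the authors' deposited table, 12 higher and 39 lower in MUT, all at the smallest p of 5e-05 and all with q = 0.0388.

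By class, the 51 called transcripts held 13 protein-coding transcripts outside the histone and ribosomal protein families, 6 higher and 7 lower. The others were 12 histone transcripts (all lower), 9 small RNAs (all lower), 10 pseudogene transcripts (6 higher, 4 lower), 2 ribosomal protein transcripts (both lower) and 5 other non-coding RNAs (all lower). The transcripts with the largest decreases in the authors' deposited table were Rps13-ps1 at -5.45 ± 1.18, 2010320M18Rik at -5.42 ± 1.11, 2610306M01Rik at -4.79 ± 1.22, Rny1 at -4.71 ± 0.07, Rps3a2 at -4.65 ± 0.77, Rny3 at -4.62 ± 0.06, Gm24407 at -4.48 ± 1.11, Gm24265 at -4.20 ± 0.93, Gm22513 at -3.91 ± 0.37 and Rpph1 at -3.73 ± 0.80. Rny1 and Rny3 are Y RNAs, and Rpph1 is the RNA component of RNase P. The small implied errors of these Y RNAs should not be read as precision. From HET to MUT the authors' deposited table had Rny3 at -0.84 ± 0.06, yet Cuffdiff's p there was 0.096. The largest increase in the authors' deposited table was that of the pseudogene Rpsa-ps10 at 4.19 ± 0.62. The other increases the naming rule takes, besides the 4 given above, were all of pseudogenes, with log2 fold changes in the authors' deposited table of 1.21 for Gm10093, 1.19 for Gm8730, 1.10 for Gm13443, 1.00 for Rps2-ps13 and 0.56 for Rpl3-ps1. Pseudogenes share sequence with their parent genes, so the split of reads between them is uncertain: the parent-like Rps2 transcript fell by 1.14 ± 0.37 while Rps2-ps13 rose in the authors' deposited table. Summed over the copies, a sum chosen after seeing the data, the log2 ratio from WT to MUT was -0.50 for Rps2 with Rps2-ps13, 0.12 for Rpsa with Rpsa-ps10 and -0.12 for Rps3a1 with Rps3a2 and Rps3a3. The remaining called mRNAs outside these families, named after their values were seen, were Lars2 at -2.07 ± 0.45, Hes2 at -1.16 ± 0.58, Cacna1g at -0.88 ± 0.52 and Ptn at 0.46 ± 0.27 in the authors' deposited table. Lars2 fell from 752 FPKM in WT to 179 FPKM in MUT. Also named after their values were seen, the mitochondrial ribosomal RNA mt-Rnr1 was called at -0.82 ± 0.34 and the non-coding Gm26917 at -1.56 ± 0.39. Whether the fall of Lars2 belongs with those of non-coding RNAs was not tested.

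**Figure D2:**
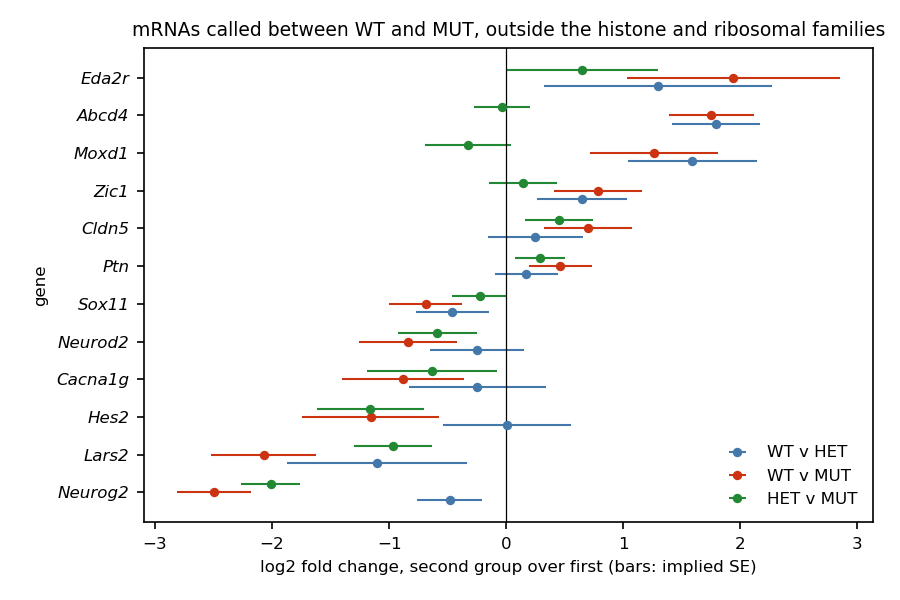
Log2 fold change (horizontal axis, second group over first) of 12 of the 13 protein-coding transcripts called between WT and MUT outside the histone and ribosomal protein families (vertical axis), in each of the 3 comparisons. Bars are the implied standard error; Abcd4 lies at 1.75 from WT to MUT and at -0.04 from HET to MUT.

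Of 30 measured rod and shared photoreceptor genes, 27 had a ratio below 0, and the list median was -0.20 (percentile 0 of the random lists). Of 27 measured neurogenic bHLH factors and partners, Neurog2, Neurod2 and Sox11 were called lower and 24 did not pass. Adjusted over the list alone, 4 members were lower, the added one being Nhlh1 with a log2 fold change of -0.80 ± 0.56 in the authors' deposited table; the list median was -0.12 (percentile 0). Neurog2 itself is on that list. Of 25 measured amacrine cell genes, 1 (Neurod2) was called lower, also when adjusted over the list alone, 24 did not pass, and the median was -0.10 (percentile 0). Retinal ganglion cell, horizontal, cone and bipolar cell genes had no called member over all rows or when adjusted over the list alone, and their medians of 0.01, 0.00, 0.01 and -0.01 lay inside the random range.

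Progenitor, proliferation and glial genes lay slightly higher without single calls. All 20 retinal progenitor genes, all 24 measured Müller glia genes and all 28 cell cycle genes failed to pass, also when adjusted over the list alone. Their medians of 0.11, 0.12 and 0.12 were outside the random range (percentiles 99.99, 99.99 and 100), with 18, 19 and 26 members above 0. The 23 Notch pathway genes had a median of 0.02 inside the random range and the 13 immediate early and heat shock genes one of 0.00, neither with a call, also when adjusted over the list alone. Of 16 measured cell death and p53 target genes, 1 was called higher over all rows and when adjusted over the list alone, the X-linked death receptor gene Eda2r at 1.94 ± 0.91 in the authors' deposited table with 0.501 FPKM in MUT, and the median was 0.11 (percentile 99.71).

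Markers of other cell types also differed between the pooled groups. All 14 measured microglia and macrophage genes had a ratio above 0 with a median of 0.43 (percentile 100); none was called over all rows, and 3 were higher when adjusted over the list alone, with log2 fold changes of 0.86 ± 0.54 for Ctss, 0.72 ± 0.42 for C1qc and 0.57 ± 0.40 for C1qa in the authors' deposited table. Of 11 measured vascular genes, Cldn5 was called, Cldn5 and Rgs5 were higher when adjusted over the list alone, and the median was 0.14, inside the random range. The 7 astrocyte genes had a median of 0.27 (percentile 99.43), the 3 blood cell genes 0.28 (percentile 98.45) and the 3 skeletal muscle genes 0.30 (percentile 97.9), with no call, also when adjusted over the list alone. Matched on length too, a choice made after seeing the data, the blood cell and skeletal muscle lists lay inside the random range (percentiles 84.99 and 93.25) and the vascular list outside it (percentile 98.71). Lens genes (9), retinal pigment epithelium and melanocyte genes (7) and stroma, cornea and ciliary margin genes (5) had medians of -0.16, -0.06 and -0.12, with no call by either correction; the last was outside the random range (percentile 2.4), and its sign turned when all members above 0 were taken (0.01).

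Histone and small RNA genes had list medians below 0 and outside the random range. Of 57 measured histone genes, 11 were called lower and 46 did not pass; adjusted over the list alone, 32 were lower and none was higher. The list median was -1.58 (percentile 0; -0.85 with a pseudocount of 1), and the largest called decreases in the authors' deposited table were Hist1h3f at -3.06 ± 1.25, Hist1h4f at -2.98 ± 1.14 and Hist1h4c at -2.84 ± 1.13. Of 56 measured small RNA genes on the list, which is set by symbol and leaves out the Y RNAs, 4 were called lower, also when adjusted over the list alone, and 52 did not pass, with a median of -2.10 (percentile 0). In the authors' deposited table Rn7sk, the 7SK RNA, fell from 358 to 27.2 FPKM. Of 79 ribosomal protein genes by symbol, 3 were called lower (Rps2, Rpl26 and Rps3a2, the last annotated as a processed pseudogene and counted as such by class above), 4 were lower when adjusted over the list alone, and the median was -0.06 (percentile 0).

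The male-expressed Y-linked gene Kdm5d summed, over 2 transcripts, to 3.73 FPKM in WT and 0.00117 FPKM in MUT. Xist, which is expressed from the inactive X chromosome of females, summed to 98.8 and 135.0 FPKM. The Y-linked Eif2s3y, under the 0.5 FPKM that a list needs, was at 0.357 FPKM in WT and 0.0142 FPKM in MUT. Measured Y-linked RNA was therefore present in WT and nearly absent from MUT. A difference in sex thus ran alongside genotype for every gene group above. Of the 5 sex-linked control genes, 2 were measured in this table, Xist (higher) and Kdm5d (lower), and neither was called by either correction. Their median was -2.40 (-0.90 with a pseudocount of 1, -3.97 with 0.01), which averages 2 opposite changes.

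The authors' Cuffdiff test gave 379 transcripts at an unadjusted p under 0.05. No transcript was called at a q-value under 0.01. The calls rested on their own number: with the correction recomputed over protein-coding transcripts without histones, or over transcripts of 1000 nt or more, both chosen after seeing the data, 0 transcripts passed, since the rows left at the smallest p were too few for a q-value under 0.05.

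**Figure D3:**
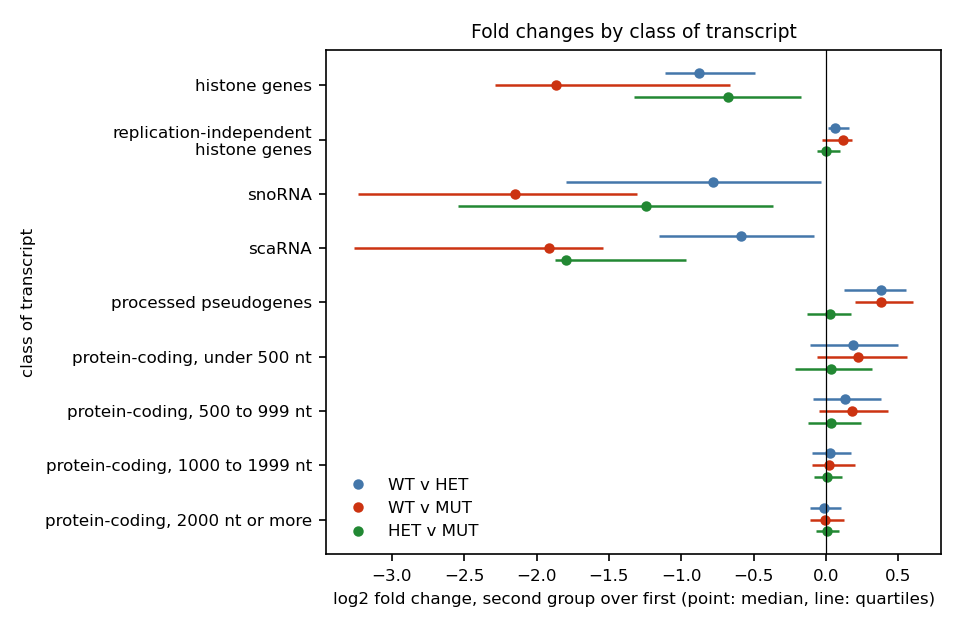
Log2 fold change (horizontal axis, second group over first) of transcripts with 1 FPKM or more by class and, for protein-coding transcripts, by length (vertical axis), in the 3 comparisons; points are medians and lines quartiles over transcripts. From WT to MUT the median is -2.15 for snoRNAs and 0.12 for replication-independent histone genes, a set chosen after the data were seen.

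**Figure D4:**
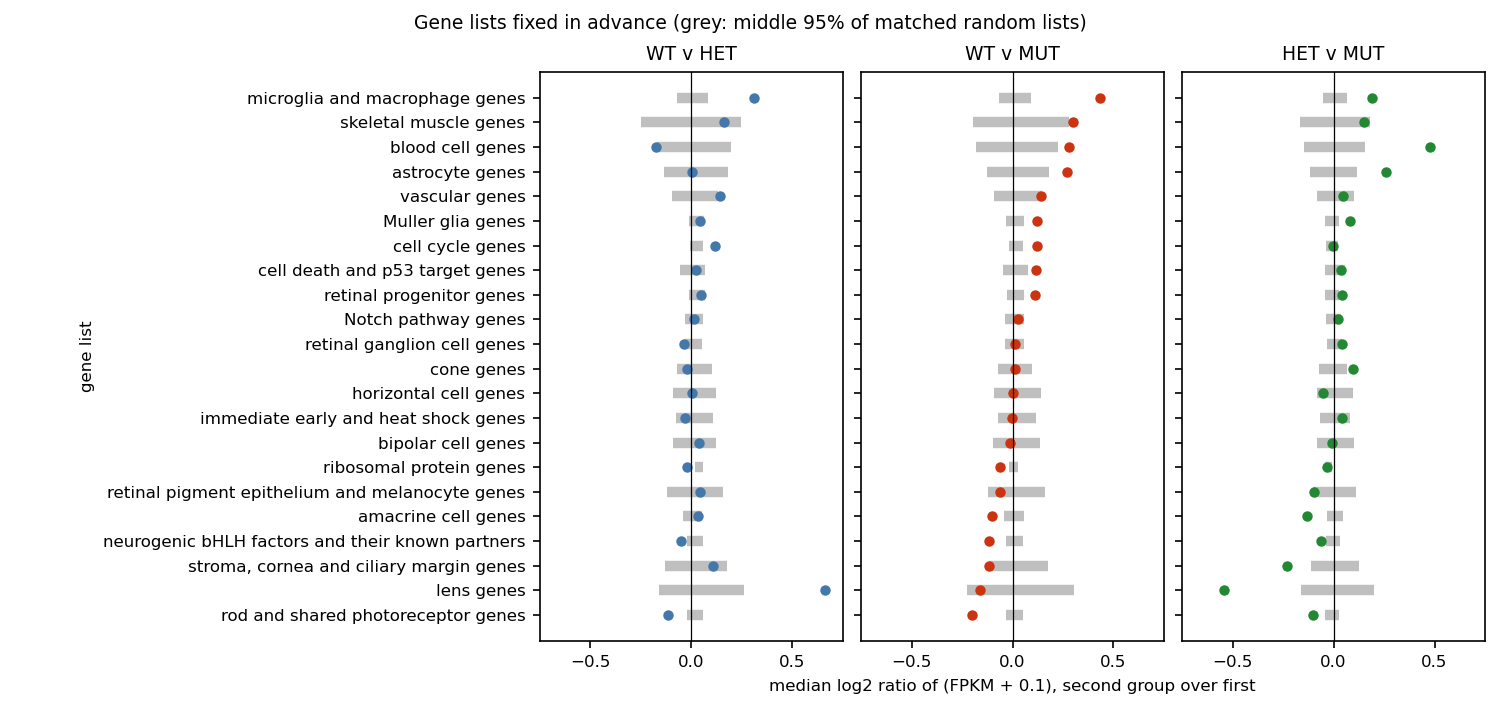
Median log2 ratio of (FPKM + 0.1) (horizontal axes, second group over first) of 22 gene lists (vertical axis) in the 3 comparisons. Grey bars span the middle 95% of 10000 random lists matched on FPKM. Microglia and macrophage genes lie at 0.43 from WT to MUT and rod and shared photoreceptor genes at -0.20.

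The comparison of WT with HET asks what changes with loss of 1 Neurog2 copy together with the presence of Cre. The mRNAs with the smallest p, chosen after their values were seen, were Abcd4 at 1.79 ± 0.37, Moxd1 at 1.59 ± 0.55, Neurog2 at -0.48 ± 0.28, Rps2 at -1.25 and Rpl26 at -0.71 in the authors' deposited table. No transcript was called by Cuffdiff at a q-value under 0.05, and the smallest q-value in the authors' deposited table was 0.0769, shared by 21 transcripts (9 higher and 12 lower in HET). Fewer rows than the 45 needed thus shared the smallest p, so no transcript could be called, whatever its change. The lack of calls is therefore no measure of how much changed. The unadjusted p was under 0.05 for 227 transcripts, 100 higher and 127 lower, and a normal approximation to the test statistic called 29. The 21 transcripts held 9 pseudogene transcripts, 5 small RNAs and no histone.

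No gene list had a member called over all rows, as no transcript was called. Rod and shared photoreceptor genes had a median of -0.11 (percentile 0), with 24 of 30 below 0, and neurogenic bHLH factors and partners one of -0.05 (percentile 0.05). Adjusted over the list alone, 2 of the 27 bHLH factors and partners were lower, Neurog2 and Sox11, the latter at -0.46 ± 0.31 in the authors' deposited table. The 25 amacrine cell genes had a median of 0.03, inside the random range. Cell cycle genes had a median of 0.12 (percentile 100) and microglia and macrophage genes one of 0.31 (percentile 100, 14 of 14 above 0), without a call in either when adjusted over the list alone. The 9 measured lens genes, which encode mostly crystallins, had a median of 0.66 (percentile 100), which became 0.34 with a pseudocount of 1 and 0.29 over the 2 genes with 2 FPKM or more, with Cryaa at 0.470 FPKM in WT and 1.11 FPKM in HET in the authors' deposited table (p = 0.013). Histone genes had a median of -0.78 (percentile 0; -0.45 with a pseudocount of 1) and small RNA genes one of -0.63 (percentile 0), with 3 and 1 members lower when adjusted over the list alone. Xist summed to 98.3 FPKM in WT and 63.2 FPKM in HET, and Kdm5d, here over 4 transcripts, to 4.95 and 7.10 FPKM.

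The comparison of HET with MUT asks what changes with loss of the second Neurog2 copy where both groups carry Cre. Adjusted over the list alone, 6 of 27 neurogenic bHLH factors and partners were lower, Neurog2 among them, and none was higher; 9 of the 27 had a ratio above 0. Besides Neurog2, the authors' deposited table gave Nhlh1 at -0.68 ± 0.43, Neurod2 at -0.59 ± 0.34, Olig2 at -0.46 ± 0.27, Ptf1a at -0.43 ± 0.31 and Nhlh2 at -0.39 ± 0.23, and none of the 27 was called over all rows. The list median was -0.06 (percentile 0.02). Of 24 measured amacrine cell genes, 3 were lower when adjusted over the list alone (Neurod2, Nhlh2 and Ptf1a, which stand on both lists), none was called over all rows, and the median was -0.13 (percentile 0).

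No transcript was called by Cuffdiff at a q-value under 0.05 between HET and MUT. The smallest p was shared by 27 rows where 44 are needed, so no transcript could be called, whatever its change. The smallest q-value in the authors' deposited table was 0.0762, shared by 27 transcripts, 5 higher and 22 lower in MUT, and 358 transcripts had an unadjusted p under 0.05; the normal approximation called 26. Protein-coding transcripts among the 27, chosen after their values were seen, included Hes2, a Hes family transcription factor, at -1.16 ± 0.46, Sema3g at -1.15 ± 0.54, Lars2 at -0.97 ± 0.33, Prss56 at -0.70 ± 0.33 and Lrrc17 at -0.52 ± 0.30 in the authors' deposited table. Creg2 at 0.56 ± 0.32 and Epas1, a hypoxia-inducible factor, at 0.43 ± 0.24 were higher in the authors' deposited table.

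Rod and shared photoreceptor genes had a median of -0.10 (percentile 0) from HET to MUT, with no call when adjusted over the list alone. Müller glia genes had a median of 0.08 (percentile 100), although Prss56, which is on that list, was its 1 member lower when adjusted over the list alone. Cell cycle genes had a median of 0.00, inside the random range. Cone genes had a median of 0.10 (percentile 99.63), although of 13 measured members 7 had a ratio above 0 and 6 below. Adjusted over the list alone, 1 cone gene was higher, the potassium channel subunit gene Kcne2. Microglia and macrophage genes had a median of 0.19 (percentile 100), astrocyte genes 0.26 (percentile 99.95) and the 3 blood cell genes 0.48 (percentile 99.99), none with a member higher when adjusted over the list alone. Lens genes had a median of -0.54 (percentile 0; -0.36 with a pseudocount of 1, -1.25 with all members above 0) and stroma, cornea and ciliary margin genes one of -0.23 (percentile 0.17; -0.11 with 2 FPKM or more), with 1 member of each lower when adjusted over the list alone (Cryaa and Col1a1). Histone and small RNA genes had medians of -0.76 (-0.31 with a pseudocount of 1, and -0.26 over the 18 histone genes with 2 FPKM or more) and -1.48 (both percentile 0), with 15 and 4 members lower when adjusted over the list alone and 1 histone gene higher. Xist, at 1.16 ± 0.47 in the authors' deposited table (p = 0.0011), was higher in MUT. It was the 1 sex-linked control gene that passed when adjusted over the list alone. Kdm5d, over 2 transcripts, summed to 5.41 FPKM in HET and 0.00117 FPKM in MUT. Measured Y-linked RNA was thus present in HET and nearly absent from MUT, beside every gene list of this comparison.

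The 3 tables were normalized separately but shared their groups. Over 26828 transcripts with 1 FPKM or more in every group, the level of WT differed between its 2 tables by a median of 0.01 on the log2 scale, and the sum of the WT to HET and HET to MUT changes differed from the WT to MUT change by a median of 0.00. No transcript was called in more than 1 comparison at a q-value under 0.05, since only WT against MUT had calls. At a q-value under 0.10, 6 transcripts were higher and 11 lower in both HET and MUT against WT, where independent lists would share 0.00293 and 0.0114. Shared WT libraries raise such overlap without any effect. A further ranking, chosen after seeing the data, took the 21 and 55 of the 31193 transcripts below with the largest absolute test statistics. They shared 15 in the same direction. In 100 simulations without effects the mean was 4.8 and the maximum 11. With 5 FPKM or more, 15 were shared against at most 13. The simulations drew transcripts independently and used implied errors that are too wide (below). They therefore cannot tell whether this overlap exceeds that of shared WT libraries alone. At a q-value under 0.10, 1 transcript was higher and 13 lower both from WT to MUT and from HET to MUT.

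Across 31193 transcripts with 1 FPKM or more in a group, the log2 fold changes of HET and MUT against WT had a covariance of 0.19, a Pearson correlation of 0.60 and a Spearman correlation of 0.66; transcripts are not independent replicates. Simulation without effects gave no usable value over all of these, since implied errors reached 22399 and simulated covariances ran from -10170 to 6232 around a mean of -132.4, with a mean correlation of 0.06. Over the 14667 transcripts with implied errors under 1, a choice made after seeing the data, the covariance was 0.031 against a simulated 0.22, and the correlation was 0.67 against a simulated 0.71. The implied errors are thus wider than the spread of these changes, and the correlation did not exceed the one simulated from them.

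Within 10 Mb of Neurog2, Neurog2 itself left out, 1 of 129 transcripts (Snhg8) was called from WT to MUT, against 47 of 30651 elsewhere (Fisher's exact test, p = 0.18). The other comparisons had no calls anywhere.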

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

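The tests chosen after the results were seen were the corrections over protein-coding transcripts without histones, over transcripts of 1000 nt or more and over autosomes, the counts at an unadjusted p under 0.05, the random lists matched on length with the mean of their medians subtracted, the overlap by largest test statistic, and the covariance over transcripts with implied errors under 1. No paired analysis was possible because the tables hold values pooled by group; replicate numbers and the first parts of the sample codes recur in all groups, and what the codes mark is not given in the sources used here. Leave-one-out and other splits of the samples could not be run, as values per sample were not analysed here, and the depth behind each value is unknown. Neurog2 kept its direction under all 9 settings tried. Of 450 list medians under alternatives, 417 moved by 0.1 or less on the log2 scale.

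The 51 transcripts called between WT and MUT became 0 at a q-value under 0.01, 0 among protein-coding transcripts without histones and 0 at 1000 nt or more, and 379 had an unadjusted p under 0.05. The normal approximation called 39, of which 13 were among the 51. The smallest p of 5e-05 sets the last 2 zeros, as fewer of the rows left share it than a q-value under 0.05 needs. At a q-value under 0.01, the zero follows from the smallest deposited q-value of 0.0388. From 0 called by Cuffdiff between WT and HET the count went to 21 at a q-value under 0.10, 29 by the normal approximation and 227 at an unadjusted p under 0.05. From 0 between HET and MUT it went to 27, 26 and 358.

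Adjusted over the list alone, the members called from WT to HET were 2 neurogenic bHLH factors and partners, 3 histone, 4 ribosomal protein and 1 small RNA genes. From WT to MUT they included 2 vascular, 3 microglia and macrophage, 32 histone, 4 neurogenic bHLH, 4 ribosomal protein, 4 small RNA, 1 amacrine cell and 1 cell death genes. From HET to MUT they were 1 cone, 3 amacrine cell, 1 Müller glia, 6 neurogenic bHLH, 1 lens, 1 vascular, 1 stroma, 1 sex-linked, 16 histone, 1 ribosomal protein and 4 small RNA genes. These corrections cover fewer tests.

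With a pseudocount of 1, list medians became 0.34 for lens genes and -0.45 for histone genes from WT to HET. From WT to MUT they became -0.90 for sex-linked, -0.85 for histone and -1.54 for small RNA genes. From HET to MUT they became -0.36 for lens, -0.79 for sex-linked, -0.31 for histone and -1.12 for small RNA genes. With a pseudocount of 0.01 they became -3.97 for sex-linked and -1.75 for histone genes from WT to MUT, and -4.98 and -0.89 from HET to MUT.

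With all members above 0, medians from WT to HET became 0.53 for lens and 0.0048 for skeletal muscle genes. From WT to MUT they became 0.42 for skeletal muscle and -2.0 for sex-linked genes, and that of stroma, cornea and ciliary margin genes turned from -0.12 to 0.0095. From HET to MUT they became -1.25 for lens and 0.35 for skeletal muscle genes. With 2 FPKM or more, medians from WT to HET became 0.29 for lens, -0.29 for blood cell, -0.0081 for stroma and -0.76 for small RNA genes. From WT to MUT they became 0.42 for skeletal muscle, -1.71 for histone and -2.30 for small RNA genes. From HET to MUT they became -0.43 for lens, -0.11 for stroma, 0.26 for skeletal muscle, -2.34 for sex-linked, -0.26 for histone and -1.63 for small RNA genes. The cause was not tested.

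At a q-value under 0.10, HET and MUT shared 6 higher and 11 lower transcripts against WT, WT to MUT and HET to MUT shared 1 higher and 13 lower, and WT to HET and HET to MUT shared 4 lower. By largest test statistic, HET and MUT shared 15 in the same direction, against 0 called in both. The covariance of 0.19 became 0.12 at 5 FPKM or more and 0.031 with implied errors under 1. At an unadjusted p under 0.05, 2 transcripts near Neurog2 passed from WT to HET and 2 from HET to MUT.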

Other observations

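All tests of explanations below were chosen after the results were seen. Among genes whose value in HET lay apart from both other groups, chosen after their values were seen, Prss56 had a log2 fold change of 0.55 ± 0.42 from WT to HET and of -0.70 ± 0.33 from HET to MUT in the authors' deposited table. Lrrc17 was at 0.77 ± 0.42 and -0.52 ± 0.30 in the authors' deposited table, and Fam132a at 0.36 ± 0.31 and -0.55 ± 0.25. The lens gene Cryaa was at 1.25 ± 1.15 and -1.44 ± 0.86 in the authors' deposited table. Zgrf1, 15.1 kb from Neurog2, was at -0.36 ± 0.34 and 0.40 ± 0.27 in the authors' deposited table; 1 of 64 genes near Neurog2 and 24 of 13566 elsewhere had this form (Fisher's exact test, p = 0.11).

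Processed pseudogenes had median log2 fold changes of 0.38 from WT to HET, 0.38 from WT to MUT and 0.03 from HET to MUT, over 272, 272 and 269 transcripts. Protein-coding transcripts between the quartiles of pseudogene lengths had medians of 0.14, 0.19 and 0.04. Rps3a2 was at 1.32 ± 0.49 from WT to HET and at -4.65 ± 0.77 from WT to MUT in the authors' deposited table, with reads uncertain between it and its near copies. The X-linked Kdm6a was at 0.39 ± 0.27 from HET to MUT in the authors' deposited table.

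Histone and small nucleolar RNAs were lower in MUT than in WT. Fewer cycling cells would lower the cell cycle list, whose median was 0.12. Loss of short transcripts as such would lower protein-coding transcripts under 500 nt, whose median was 0.22. Only 21 of those were under 200 nt (median 0.38), whereas the called small nucleolar RNA Snord22 is 126 nt long. A loss of RNA that short was therefore hardly tested and stays open. A lower yield of RNA without a poly(A) tail in the MUT libraries stays open as a candidate explanation: snoRNAs had a median of -2.15, while transcripts of replication-independent histone genes, which carry a tail, had one of 0.12. The set of those histone genes was chosen after the data were seen, and snRNAs went both ways, with a median of -0.58 and 11 of 26 higher. An effect of genotype on these RNAs was not tested and also stays open.

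The 13 mRNAs called between WT and MUT outside the histone and ribosomal protein families moved in groups that differed in Y-linked RNA. Fewer male retinas in MUT would turn their changes from WT to HET the other way, as for Xist; their median in the direction of the WT to MUT change was 0.46, where a simulation of shared WT libraries without any effect, from implied errors that are too wide, gave 0.74. Sex would also make their changes larger from HET to MUT than from WT to MUT, and 12 of 13 were smaller. These mRNAs were selected by their change from WT to MUT, which alone tends to make that change the larger. Only Abcd4 was smaller by more than 2 implied errors on each side. Sex thus stays open for the others, among which Neurog2 was the targeted gene. A shift of short against long transcripts would shrink these changes once removed, and 98.2% of their median size was left. These mRNAs were all 1416 nt or longer, where the median shift was at most 0.055. The subtraction could therefore remove little, and it shows only that the shift was small at these lengths. Loss of Neurog2 and the presence of Cre stay open.

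Abcd4 was higher in HET and MUT than in WT. The comparison of HET with MUT, which leaves WT out, was taken as the test of sex after other rules had been tried. A difference in the share of male retinas would make that change larger than the 1.75 from WT to MUT, but it was -0.037 (implied error 0.24). An extra copy of genomic sequence carried by the Cre transgene needs this near equality and stays open for Abcd4. Near equality does not single out such a copy, as anything that sets WT apart would give it. Zic1 was at 0.65 from WT to HET, 0.79 from WT to MUT and 0.14 from HET to MUT in the authors' deposited table. Noise in the shared WT libraries would also move both changes from WT alike. What the transgene carries is not given in the sources used here. An effect of the Neurog2 genotype or of Cre itself was not tested and also stays open.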
